A study of Mus musculus with 4 samples.

How the data were processed

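Droplet single-cell RNA-seq of CD4 T cells from pooled peripheral lymph nodes of Apoe-deficient mice was analysed in 4 samples. These mice lack apolipoprotein E and are a standard model of atherosclerosis. The tetramer used for sorting is a set of linked MHC class II molecules loaded with a peptide of apolipoprotein B (ApoB), the main protein of low-density lipoprotein, and it binds T cells whose receptor recognises that peptide. Per the labels' protocols, CD4 T cells were first enriched by removing other cells with magnetic beads. All cells were then incubated with the tetramer in 2 colours, APC and PE. Live CD45+ TCR-alpha/beta+ CD4+ cells without markers of B, CD8, NK, myeloid or erythroid cells were sorted. The ApoB-negative group (no tetramer binding) has 3 pools of 10 mice each, and the ApoB-positive group (binding in both colours) has 1 pool of 30 mice. The labels do not say whether both groups came from the same mice. Each pool was 1 droplet preparation, so for the ApoB-positive cells group and library cannot be separated.

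The deposited files hold raw UMI counts per gene and barcode, not normalised, made by the authors with Cell Ranger and STAR on the mouse build mm10, per the submitters' processing notes. Versions, the annotation and the rule by which barcodes were called cells are not given in the sources used here. A UMI is a tag added to each molecule before amplification, so that copies of 1 molecule count once. The files list 27998 genes, of which 27645 identifiers matched a symbol in the gene table. T-cell receptor segments and constant regions and immunoglobulin constant regions are not in that gene list. Coordinates were taken from a mouse gene annotation of the same assembly (mm10).

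The 15186 deposited barcodes held 12037800, 15298545 and 15256576 UMIs in ApoB-negative pools 1, 2 and 3 and 11489886 in the ApoB-positive pool. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored against simulated doublets (2 per cell, an own implementation of the Scrublet approach), and the highest scores were removed at a rate of 0.8% per 1000 barcodes of the library. This removed 81, 169 and 173 barcodes from the negative pools and 62 from the positive pool. The retained 14228 cells held 11511628, 14374038, 14194378 and 11057248 UMIs, in the same order.

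For clustering, each cell was scaled to 10000 counts, and 2000 variable genes seen in at least 10 cells were taken, without receptor segments, mitochondrial, ribosomal, Xist and Y-linked genes. Leiden clustering ran on 30 principal components and 15 neighbours at resolution 1 with seed 1, without batch integration (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). It gave 13 clusters. A cluster took a name from fixed markers when at least 3 of them were among its 20 leading genes and no other class had more in its top 10 genes. Genes were ranked by fold with a pseudo-CPM of 10, among genes with a UMI in at least 5% of the cluster's cells. Clusters 0, 1, 3, 4, 5 and 8 took no name against all other cells. They were named naive-like against the clusters that had a name, a reference chosen after the data had been seen. The naive-like class and the class of other T cells, with the tests that use them, rest on this choice. No cluster took the name of B, myeloid, stromal or erythroid cells, so all were kept as T cells.

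Raw counts were summed per library over all T cells, and over naive-like, Treg-like and all other T cells. These sums were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM factors and filterByExpr, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A single ApoB-positive pool leaves 2 residual degrees of freedom. The spread therefore comes from the 3 negative pools, moderated over genes, and the lone pool is assumed to vary like them. P-values rest on the spread between the negative pools of mice, in part shared over genes. In the Treg-like and effector-memory-like fits the moderation was complete. There each gene took the spread shared over genes and not its own, so those p-values do not measure the gene's own spread between pools. An exact permutation of 1 library against 3 cannot go below p = 0.25, so none is given. Differences in effect between classes were tested as interaction terms with the library as a block. Cells per cluster were tested with the same edgeR model, for clusters with at least 10 cells.

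Of 24 gene lists, 19 had the 3 tested members that camera (limma 3.58.1) needs. Camera compares a list with all other genes at a preset inter-gene correlation of 0.01, and it was repeated with an estimated correlation. Fry tests whether a list's genes move 1 way on balance. The lists were naive, Treg, Th1/effector, Th17, Th2, follicular helper (Tfh), activated/memory, T-cell receptor signalling, anergy/exhaustion, chemokine receptors and homing, interferon response, proliferation, cholesterol, stress/dissociation, CD8, NK/NKT/gamma-delta, B cell, myeloid, erythroid/platelet, stroma, sex, mitochondrial, ribosomal and T-cell receptor segments. Member counts are given over all genes tested and adjusted over the list alone. Several lists share genes with each other, such as Cxcr3, Ctla4 and Pdcd1.

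The named genes are 18 key genes, the 8 largest rises and 8 largest falls per main comparison (5 and 5 within a class), and up to 4 members with the smallest p per list. A rise or fall needed an adjusted p under the threshold, an ApoB-positive level outside the range of the 3 negative pools and at least 50 UMIs over the 4 samples, and receptor segments, mitochondrial, ribosomal and predicted genes were left out. Genes named outside this rule are said to be chosen after their values were seen. Levels are CPM values of the edgeR fit (summed UMIs of a gene over the total of the genes tested in that comparison, times the TMM factor), with mean and SD over the 3 negative pools. Folds are log2 values of the edgeR fit ± SE. Where 1 side holds 1 to 3 UMIs, the ratio of UMIs over all UMIs of each group, without TMM factors, is given with its 95% exact counting interval, and against 0 UMIs a bound from 3 counts over the group. Shares have 95% Clopper-Pearson intervals. Intervals and bounds cover counting error only.

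For shares of cells with a UMI, each cell was thinned to 2200 UMIs, which left out 116, 341 and 410 cells of the negative pools and 83 of the positive pool. The seed of this draw was changed after first values had been seen, so ranges over 5 draws are given for the ApoB-positive shares of main interest. Naive-like cells served as background for RNA outside cells, since no B-cell cluster was found.

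Groups, tests, gene lists, markers, the naming rule and the other settings listed next were fixed before the data were examined. The reference by which naive-like clusters were named is an exception. The other settings were DESeq2 size factors, total counts only, no low-count filter, the Wald test of DESeq2 1.42.0, no doublet removal, all barcodes, at least 800 genes with at most 5% mitochondrial UMIs, resolutions of 0.6 and 1.5, clustering without the called genes, equal shares of naive-like, Treg-like and other cells, thinned sums and each negative pool left out. Added after seeing the data were the comparison within effector-memory-like cells and its interaction test, the fit without those cells, the class-level test of shares, the shares outside those cells, the mix of naive-like clusters, the share of cells with at least 2 markers, the classes of Foxp3 cells and the draws of the thinning.

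On simulated counts, changes of log2 fold 1 and 2 were recovered for 78.3% and 96.7% of changed genes over all T cells (10664 genes). For naive-like cells the values were 79.0% and 95.4% (10086 genes), for Treg-like cells 38.0% and 76.2% (6052), for other T cells 68.7% and 95.5% (8949), and for effector-memory-like cells 64.1% and 82.8% (3128). A simulated cluster raised 10-fold was found in 100 of 100 draws. Of tests of the other clusters, whose shares then fall, 9.24% had an unadjusted p under 0.05. The false-positive rate is unknown, so share calls near the threshold need caution. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.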

Results

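CD4 T cells that bound an ApoB peptide tetramer were compared with CD4 T cells of the same kind of sort that did not bind it. ApoB is the main protein of low-density lipoprotein, and the mice were Apoe-deficient C57BL6/J animals. The comparison asks what state T cells specific for this self-protein are in. The data are UMI counts per cell in 3 ApoB-negative pools and 1 ApoB-positive pool. After filtering, the negative pools held 3005, 4313 and 4251 cells with median depths of 3756, 3241 and 3258 UMIs per cell. The ApoB-positive pool held 2659 cells with a median of 3942 UMIs. Total UMIs of retained cells ran from 11057248 to 14374038 per library. Median mitochondrial shares were 2.45%, 2.58%, 2.61% and 2.40%, with the ApoB-positive pool last. There is no second ApoB-positive pool, so its values carry counting intervals or model errors, and errors of negative levels are SDs over 3 pools (n = 3).

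The cells looked like sorted CD4 T cells in all 4 libraries. A Cd3e UMI, from a subunit of the T-cell receptor complex, was found in 78.1%, 71.8% and 72.8% of cells of the negative pools and in 76.0% of ApoB-positive cells. Cd4 was found in 42.5%, 38.8%, 38.6% and 46.9%. Of the cells gated out, the B-cell genes Cd19 and Cd79a had 0 UMIs in every library and 13, 20, 18 and 9 UMIs, Itgam, of myeloid cells, had 14, 9, 8 and 4, and Cd8a, of CD8 T cells, had 3, 5, 5 and 1. Cd8b1, also of CD8 T cells, was not rare, with 218, 285, 270 and 215 UMIs in 6.36%, 6.07%, 5.76% and 6.96% of cells. Lyz2, a lysozyme gene of myeloid cells, had 0, 0 and 1 UMIs in the negative pools and 41 in the ApoB-positive pool, all in 13 cells. Apoe, the gene disrupted in these mice, had 14, 11, 16 and 11 UMIs. All groups carry that disruption, and a tag from the 3' end of the transcript does not test whether it is present.

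Effector-memory-like T cells made up far more of the ApoB-positive library than of any negative pool. Their clusters were led by S100a4, Ccl5, Cxcr3, Nkg7 and Cxcr6, genes of cells that have met antigen and home to inflamed tissue, and Maf and the Treg-cell genes Ikzf2 and Nrp1 were among the leading genes of the larger cluster, 9. Both clusters together held 21.4% of ApoB-positive cells (95% interval 19.9 to 23.0%) and 1.63% ± 0.232 of negative cells (SD, n = 3), a ratio of 13.1. Naive-like cells, led by Igfbp4, Dapl1 and Lef1, made up 59.3% (57.5 to 61.2%) against 73.5% ± 2.66. Proliferating-like cells, led by Birc5, Pclaf and Ccnb2, made up 2.33% (1.79 to 2.98%) against 1.25% ± 0.201. Treg-like cells, led by Il2ra, Foxp3 and Ikzf2, made up 4.40% (3.65 to 5.25%) against 6.38% ± 1.17.

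In the edgeR test of cells per cluster, both effector-memory-like clusters passed and the other 11 did not. Cluster 9 held 20.1% of ApoB-positive cells (18.6 to 21.7%) against 1.58% ± 0.243, a log2 fold of 3.66 ± 0.22 (adjusted p = 0.000229). Cluster 12, with Plac8, Cxcr6 and Xcl1 in front, held 1.28% (0.887 to 1.78%) against 0.0533% ± 0.0115, a log2 fold of 4.53 ± 0.29 (adjusted p = 0.000229), and it missed the threshold without negative pool 2 (adjusted p = 0.0769). In the test by class, added after seeing the data, effector-memory-like cells rose (log2 fold 3.69 ± 0.23, adjusted p = 1.14e-08) and naive-like cells fell (-0.31 ± 0.08, adjusted p = 0.00912). Proliferating-like cells rose (0.89 ± 0.33, adjusted p = 0.0385). Without negative pool 2 the naive-like call was lost (adjusted p = 0.159), and the proliferating-like call was lost without pool 1 (0.19) or pool 2 (0.161). Treg-like (-0.55 ± 0.27, adjusted p = 0.0788), interferon-like (8.09% against 11.4% ± 1.10, adjusted p = 0.0604) and immediate-early-like cells (4.44% against 5.79% ± 0.385, adjusted p = 0.183) did not pass. Shares sum to 100%, so a rise of 1 class lowers the others. Among the cells outside the effector-memory-like clusters, naive-like cells were 75.5% against 74.8% ± 2.53 (log2 fold 0.015, adjusted p = 0.881), so no naive-like fall was left there in this clustering. Among the same cells the proliferating-like fold was 1.21 ± 0.46 without passing (adjusted p = 0.122), and cluster 5 alone passed (0.88 ± 0.17, adjusted p = 0.0351). Other clusterings differed. At resolution 1.5 naive-like cells outside the effector-memory-like clusters were 52.8% against 68.8% ± 0.680 (log2 fold -0.38, edgeR adjusted p = 2.09e-09). This p uses a spread shared over classes. Part of the effector-memory-like cells counts as Treg-like there. After clustering without the called genes the shares were 57.2% and 61.6% ± 0.877 (edgeR adjusted p = 0.103).

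The genes that define the effector-memory-like clusters also differ between the groups, so cells were clustered again without all genes called between the groups. An effector-memory-like cluster then held 17.0% of ApoB-positive cells (15.6 to 18.5%) and 6.15% ± 0.436 of negative cells, a ratio of 2.77 (log2 fold 1.47, adjusted p = 0.00016). Naive-like cells made up 47.4% against 57.8% ± 0.719, proliferating-like 1.88% against 1.07% ± 0.228 and Treg-like 7.52% against 6.25% ± 1.29. Of the 761 effector-memory-like cells of all 4 libraries, 41.0% fell into the effector-memory-like cluster of this second clustering and 26.7% into its Treg-like cluster. These cells made up 58.9% of the ApoB-positive and 5.56%, 5.28% and 8.23% of the negative cells of that second effector-memory-like cluster. Without them it held 186 of 2659 ApoB-positive cells (6.05 to 8.03%) against 5.76% ± 0.491, a ratio of 1.21. Without any clusters, 15.5% of thinned ApoB-positive cells (14.1 to 16.9%, 398 of 2576) held at least 2 of 17 effector-memory markers, against 1.82% ± 0.0940 in the negative pools (23.3% against 3.66% ± 0.635 with all UMIs). The ratio at equal depth was 8.49, and 5 draws of the thinning gave 8.09 to 8.83. Naive-like cells, the background for this measure, reached 2.05% in the ApoB-positive pool and 1.35%, 0.827% and 0.978% in the negative pools, or 7.10% and 3.39%, 1.56% and 1.98% with all UMIs. Over 5 draws it ran from 2.05 to 2.50% in the ApoB-positive pool.

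**Figure D1:**
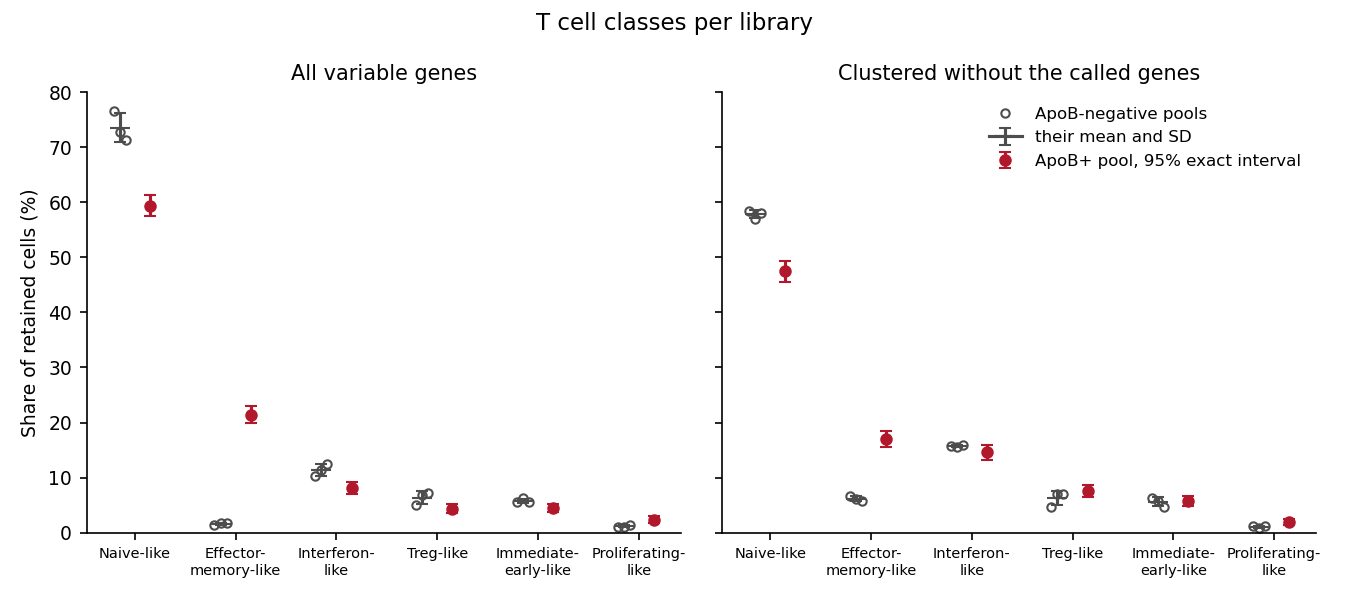
Share of retained T cells (percent) in each T-cell class, with all variable genes on the left and after clustering without the called genes on the right. Open circles are the 3 ApoB-negative pools with their mean and SD, and the red point is the ApoB-positive pool with its 95% exact interval, which reaches 21.4% against 1.63% for effector-memory-like cells on the left and 17.0% against 6.15% on the right.

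Over all CD4 T cells, Ccl5, S100a4, Cxcr6 and Ifng were among the 8 largest rises in the ApoB-positive pool. Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), a chemokine of memory and effector T cells, stood at 105 CPM against 2.77 ± 0.563 (log2 fold 5.22 ± 0.11, adjusted p = 3.71e-14). S100a4 (ENSMUSG00000001020, chromosome 3, 90603771 to 90606045), a calcium-binding protein of memory cells, stood at 107 against 4.10 ± 2.24 CPM (4.66 ± 0.18, adjusted p = 7.36e-11). Cxcr6 (ENSMUSG00000048521, chromosome 9, 123806475 to 123811760), a homing receptor of tissue-bound T cells, stood at 26.8 against 1.00 ± 0.447 CPM (4.68 ± 0.22, adjusted p = 7.72e-10). Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), which encodes interferon gamma, stood at 9.93 against 0.331 ± 0.111 CPM (4.87 ± 0.32, adjusted p = 5.25e-08). Ccr10, a chemokine receptor of skin-homing T cells, had 81 UMIs against 2 over the negative pools, a ratio of 147 (39.3 to 1230). Myo1f, a myosin of immune cells (log2 fold 4.70), the galectin gene Lgals3 (4.60) and Birc5, a gene of dividing cells (4.27), complete the 8 largest rises.

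Falls were smaller. Gsta4, a glutathione transferase, stood at 1.13 CPM against 4.72 ± 1.34 (log2 fold -2.07 ± 0.41, adjusted p = 0.00485) and Tmem108 at 7.05 against 15.0 ± 0.483 CPM (-1.09 ± 0.16, adjusted p = 0.000325). The other 6 of the 8 largest falls were Trpm1 (-2.16), Itih5 (-1.86), Lrrc32 (-1.34), Cldn10 (-1.19), Mmp11 (-1.11) and Oas2 (-1.05). Lrrc32 encodes a surface protein of Treg cells that holds latent TGF-beta. Its call and that of Trpm1 were lost without negative pool 2 (adjusted p 0.0968 and 0.171). By the DESeq2 Wald test all 6 were lost, at adjusted p 0.357 (Trpm1), 0.0544 (Itih5), 0.324 (Lrrc32), 0.249 (Cldn10), 0.422 (Mmp11) and 0.304 (Oas2). Mmp11 was also lost without doublet removal (0.0614) and with all deposited barcodes (0.0691), and Lrrc32 with sums thinned to the lowest total (0.0587). With the class shares of the negative pools, Trpm1 (-1.90, adjusted p = 0.186) and Mmp11 (-0.97, 0.169) lost the call at nearly the same fold, while Lrrc32 stood at -0.80 (0.319). Without the effector-memory-like clusters Gsta4 (-1.87, 0.0832), Trpm1 (-2.12, 0.176), Lrrc32 (-1.59, 0.0954), Mmp11 (-0.80, 0.336) and Oas2 (-0.68, 0.362) were lost.

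In total 594 of 10690 genes passed, 417 higher and 177 lower, and all genes said here to have risen or fallen lay outside the range of the 3 negative pools. With total counts only in place of TMM factors, 621 were higher and 91 lower. Left-out libraries moved the count: 1022 genes passed without negative pool 1 and 344 without pool 2. It fell to 102 (76 higher, 26 lower, 97 of them among the 594) once the effector-memory-like clusters were removed. With every library brought to the negative pools' shares of naive-like, Treg-like and other cells it was 240. The mix within the other cells was left as it was. Effector-memory-like cells were 569 of 964 ApoB-positive other cells, so the ApoB-positive sum still held a larger share of them than the negative sums. Of 72 genes of the naming rule called over all cells, the DESeq2 Wald test kept 51, the class shares of the negative pools 51 and the sums without the effector-memory-like clusters 26.

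Among the key genes, Ifng, Cxcr3, Tbx21, Rorc, Ccr6, Cxcr5, Ctla4, Pdcd1 and Cd44 were higher in the ApoB-positive pool, while the Treg regulator Foxp3 did not differ beyond error. The Th1 homing receptor gene Cxcr3 (ENSMUSG00000050232, chromosome X, 101731535 to 101734269) rose from 2.52 ± 0.767 to 34.9 CPM (log2 fold 3.80 ± 0.18, adjusted p = 7.72e-10). Tbx21, the regulator of Th1 cells, rose by 3.22 ± 0.60 (adjusted p = 0.00294), and Rorc, the regulator of Th17 cells, by 3.76 ± 0.72 (adjusted p = 0.00363). Higher levels were also found for Ccr6 (2.86 ± 0.43), the follicular receptor gene Cxcr5 (2.76 ± 0.29), the inhibitory receptor genes Ctla4 (1.71 ± 0.16) and Pdcd1 (1.49 ± 0.15), and Cd44, an activation marker (1.48 ± 0.11). The DESeq2 Wald test did not call Tbx21 (adjusted p = 0.0780) or Rorc (0.101). With the class shares of the negative pools the calls of Tbx21 (log2 fold 2.20, adjusted p = 0.285), Ifng (1.69, 0.367), Ccr6 (1.76, 0.227) and Pdcd1 (0.72, 0.0850) were lost, and without the effector-memory-like clusters those of Cxcr5 (1.83, 0.156) and Pdcd1 (0.31, 0.771), where Tbx21, Rorc and Ccr6 had too few UMIs to be tested. Sell (ENSMUSG00000026581, chromosome 1, 164061982 to 164084181), which encodes the lymph node homing receptor CD62L, fell from 225 ± 17.4 to 154 CPM (-0.55 ± 0.08, adjusted p = 0.000308). Ccr7, the other homing receptor of naive cells, fell by 0.24 on the log2 scale (adjusted p = 0.0408), a call lost without negative pool 2 (0.0994), with total counts only (0.166), by the DESeq2 Wald test (0.18), with stricter cell filters (0.0530), with thinned sums (0.0608) and with the class shares of the negative pools (0.750). It changed sign without the effector-memory-like clusters (0.018). Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) stood at 19.3 CPM against 16.1 ± 3.71 (0.24 ± 0.18, adjusted p = 0.568). Il2ra (-0.02 ± 0.16), Bcl6 (0.36 ± 0.28), Gata3 (0.12 ± 0.08) and Nr4a1 (-0.04 ± 0.14) did not pass. Il10 and Il17a had too few UMIs to be tested.

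Lists of effector, memory and helper T-cell genes rose as groups over all CD4 T cells. Of 12 Th1/effector genes 11 rose and 0 fell (the same adjusted over the list alone), with Nkg7, a granule protein gene, at a log2 fold of 3.31 ± 0.14 (camera, adjusted p = 7.11e-14; adjusted p = 0.12 with an estimated correlation). Activated/memory genes had 12 of 15 higher and 1 lower, Emp3 (-0.25, named after its value was seen), and 13 and 1 adjusted over the list alone. Their examples are the integrin gene Itgb1 (2.50 ± 0.09), S100a6 (3.85 ± 0.20) and S100a11 (1.23 ± 0.06), with camera at adjusted p = 4.72e-12 and 0.12 with an estimated correlation. Follicular helper genes had 12 of 14 higher and 0 lower, with the same counts adjusted over the list alone (adjusted p = 1.04e-10; adjusted p = 0.12 with an estimated correlation). Maf, a transcription factor of follicular helper and other effector T cells, stood at 38.1 CPM against 4.94 ± 1.09 (2.93 ± 0.15), and Tbc1d4 rose by 1.08 ± 0.11. The calls of Nkg7 (0.38, adjusted p = 0.849) and Tbc1d4 (0.30, 0.554) were lost without the effector-memory-like clusters.

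Of 8 Th17 genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), including the transcription factor gene Rora (1.96 ± 0.16) and Tmem176a (1.42 ± 0.25), while Ltb4r1 had 19 UMIs against 2, a ratio of 34.4 (8.31 to 305). By the DESeq2 Wald test Tmem176a (0.118) and Ltb4r1 (0.0646) were not called. Camera gave adjusted p = 5.84e-08, and 0.12 with an estimated correlation. Th2 genes had 4 of 6 higher and 1 lower on both scales, over all genes and adjusted over the list alone. The 4 were Ccr4 (3.99 ± 0.36), Il9r (3.94 ± 0.40), Il4 (4.03 ± 0.53) and Il1rl1 (3.02 ± 0.64), and the lower 1 was Il4ra (-0.31, named after its value was seen), with camera at adjusted p = 0.00337 and 0.164 with an estimated correlation. Chemokine receptor and homing genes had 12 of 19 higher and 1 lower, Ccr7 (13 and 2 adjusted over the list alone), with Ccr2 at 3.74 ± 0.31 (adjusted p = 8.08e-08; adjusted p = 0.12 with an estimated correlation). Anergy/exhaustion genes, with the inhibitory receptor gene Lag3 at 2.56 ± 0.23 and Nt5e at 1.39 ± 0.14, had 6 of 12 higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 3.86e-07, and adjusted p = 0.162 with an estimated correlation). Without the effector-memory-like clusters the Th17 (adjusted p = 0.144) and Th2 (0.278) lists were not called. Rora stood at 0.23 there (adjusted p = 0.870), Tmem176a at 0.33 (0.820), Ccr4 at 2.43 (0.0954), Lag3 at 1.68 (0.0967) and Nt5e at 0.68 (0.114).

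Proliferation genes rose, with 10 of 15 higher and 0 lower (11 and 1 adjusted over the list alone). Pclaf rose by 3.51 ± 0.31, Ccnb2 by 3.77 ± 0.35 and Hmgb2 by 0.86 ± 0.07, and camera gave adjusted p = 4.44e-09, or 0.12 with an estimated correlation. NK/NKT/gamma-delta genes had 3 of 6 higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.000124, and adjusted p = 0.162 with an estimated correlation). The 3 were Klrk1 (29 UMIs against 2, ratio 52.6, 13.3 to 455), Klrb1c (30 against 3, ratio 36.2, 11.3 to 186) and Zbtb16 (13 against 3, ratio 15.7, 4.32 to 85.9). The Zbtb16 call was lost without negative pool 2 (adjusted p = 0.0744), and by the DESeq2 Wald test the calls of Zbtb16, Klrb1c and the Th2 gene Il1rl1 were lost. Effector CD4 T cells can carry the first of these receptors, and Zbtb16 is the regulator of NKT cells. Gzma stood at 1.09 ± 0.40 (adjusted p = 0.165). The NK/NKT/gamma-delta list was not called without the effector-memory-like clusters (adjusted p = 0.177).

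Naive T-cell genes fell as a group, 6 of 15 lower and 0 higher (7 and 0 adjusted over the list alone). The fall of Igfbp4 was the steepest of the 4 named members, from 578 ± 42.7 to 326 CPM (log2 fold -0.82 ± 0.07), beside Lef1 (-0.51 ± 0.06), Sell and Satb1 (-0.44 ± 0.07). Camera gave adjusted p = 1.9e-05, and 0.12 with an estimated correlation. Ribosomal protein genes fell by little, with a median log2 fold of -0.15, 37 of 85 lower and 0 higher (56 lower and 3 higher adjusted over the list alone). Rpl12 stood at -0.32 ± 0.05, Rpl8 at -0.26 ± 0.04, and Rps24 and Rps4x at -0.25 each (adjusted p = 1.25e-08; adjusted p = 0.265 with an estimated correlation). Without the effector-memory-like clusters neither list was called (adjusted p 0.177 and 0.576). Igfbp4 (-0.50) and Sell (-0.36) kept their calls there, while Lef1 (-0.25, adjusted p = 0.0799), Satb1 (-0.19, 0.297), Rpl12 (-0.18, 0.137), Rpl8 (-0.12, 0.396), Rps24 (-0.11, 0.418) and Rps4x (-0.10, 0.480) lost theirs. Camera thus called 11 of 19 lists at the preset correlation and 0 with an estimated one, where 7 lists had an unadjusted p under 0.05. By fry, which tests each list against no change, all 11 but the NK/NKT/gamma-delta list (adjusted p = 0.0573) passed, as did the myeloid (0.0443) and receptor signalling (0.0456) lists.

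Treg genes did not move as a group (camera, adjusted p = 0.139). Of 14 members 5 rose and 2 fell (6 and 2 adjusted over the list alone). Ctla4, Capg (0.78 ± 0.08), Nrp1 (1.28 ± 0.17), Il2rb (0.98 ± 0.16) and Itgae (1.88, named after its value was seen) rose, while Lrrc32 and Gpr83 (-0.84, named after its value was seen) fell. Among 17 T-cell receptor signalling genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.0934). The costimulatory receptor gene Icos rose to 57.7 CPM from 22.4 ± 3.49 (1.35 ± 0.11), Bhlhe40 by 1.90 ± 0.29 and Cd200 by 0.72 ± 0.12, while Cd5, a brake on receptor signalling, fell (-0.44 ± 0.07). Of 17 interferon response genes 2 rose (Gbp2 0.38, Ifi27l2a 0.27) and 2 fell (Irf7 -0.28, Usp18 -0.50), with the same counts adjusted over the list alone (adjusted p = 0.557). These 4 calls were lost without negative pool 2 (adjusted p 0.0863, 0.212, 0.205 and 0.163) and by the DESeq2 Wald test (0.422, 0.994, 0.507 and 0.240). None of 16 cholesterol genes passed on either scale, over all genes or adjusted over the list alone, with Dhcr24 (-0.59), Scd2 (0.20), Msmo1 (-0.14) and Abcg1 (-0.10) as the members with the smallest p (list adjusted p = 0.149). Of 18 stress/dissociation genes Fosb alone rose (0.96 ± 0.14), also adjusted over the list alone (list adjusted p = 0.252). Without the effector-memory-like clusters the calls of Capg (0.36, adjusted p = 0.0692), Nrp1 (0.057, 0.964), Il2rb (0.12, 0.907), Bhlhe40 (0.27, 0.907), Cd200 (0.30, 0.492) and Fosb (0.56, 0.176) were lost.

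Markers of other cell types were few and low. Among 7 B-cell genes 3 rose (4 adjusted over the list alone), and these are genes of antigen presentation rather than of B cells alone: Cd74 (0.97 ± 0.19), H2-Aa (2.65 ± 0.72, lost without negative pool 2) and H2-Eb1 (3.25 ± 0.89, lost without pool 3), with a list adjusted p of 0.168 and adjusted p values of 0.195 and 0.0566 without those pools. The DESeq2 Wald test called none of these 3 (0.0538, 0.617 and 0.632), and Cd74 stood at 0.22 (adjusted p = 0.818) without the effector-memory-like clusters. Of 4 myeloid genes Lyz2 rose, with a ratio of 149 (25.2 to 6011), also adjusted over the list alone (list adjusted p = 0.299). Mitochondrial genes had 0 of 13 higher and 1 lower, mt-Nd1 (-0.27 ± 0.05), or 2 higher and 6 lower adjusted over the list alone (list adjusted p = 0.183). Lists with fewer than 3 tested members gave Cd8b1 at -0.06 (adjusted p = 0.863), Pecam1, of endothelium, at -0.19 (0.193), and Xist at -0.11 (0.421) and Tsix at 0.13 (0.739), all of which failed, also adjusted over the list alone. No erythroid/platelet gene had enough counts to be tested, and the list of receptor segments had 0 members in the files.

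**Figure D2:**
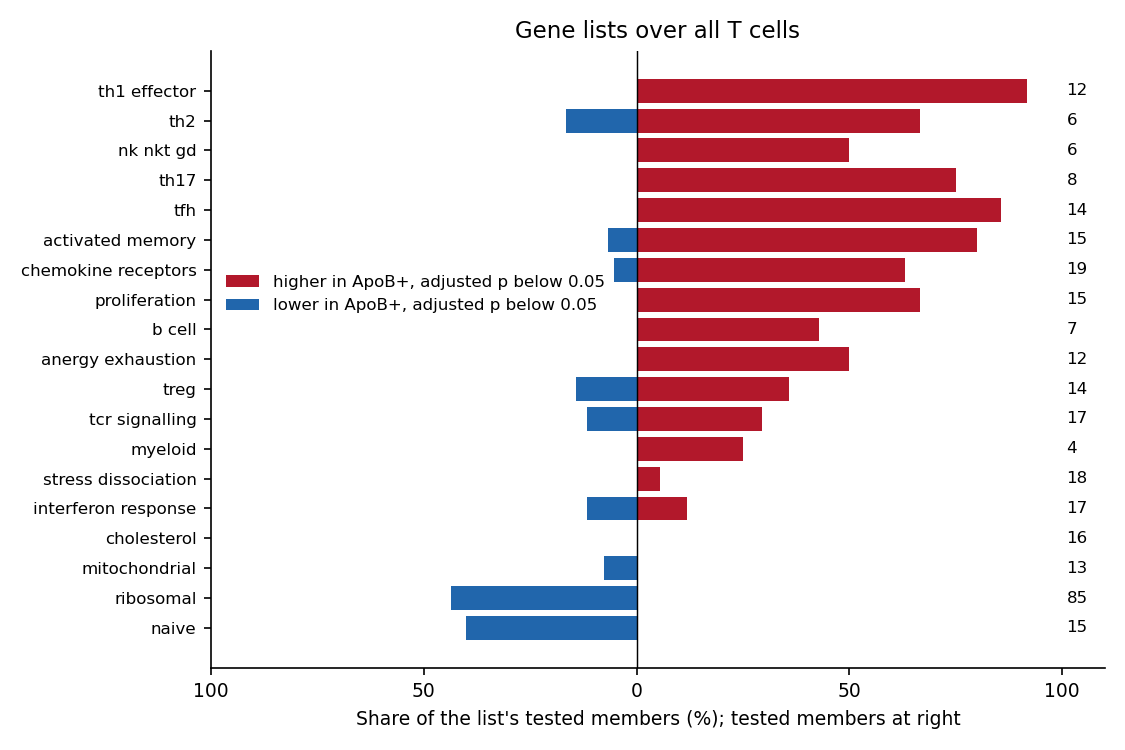
Percent of tested members called higher (red) or lower (blue) in the ApoB-positive pool, for 19 gene lists over all CD4 T cells, sorted by median log2 fold, with the number of tested members at the right. Th1/effector genes stand at 11 of 12 higher, and naive genes at 6 of 15 lower.

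Within naive-like cells few genes differed, and the groups hold different mixes of naive-like clusters. Cluster 5, led by Il7r, Klrd1 and Myo6, was 14.3% of ApoB-positive naive-like cells against 7.92%, 7.45% and 8.24%. At resolution 1.5 cluster 18, led by Capn3, H2-Oa and Wnt10a and with Ctla4 among its leading genes, was 5.96% against 0.609%, 0.956% and 0.890%. Cd5 (ENSMUSG00000024669, chromosome 19, 10717116 to 10739002), a receptor whose level follows the strength of self-recognition, fell from 155 ± 5.00 to 90.6 CPM (log2 fold -0.77 ± 0.08, adjusted p = 0.000136). Its relative Cd6 fell from 146 ± 11.3 to 91.7 CPM (-0.67 ± 0.09, adjusted p = 0.00125). Sox4 (-0.67 ± 0.14), the diacylglycerol kinase gene Dgkd (-0.64 ± 0.13) and Chchd10 (-0.60 ± 0.10) also fell. The rises were S100a4, from 0.443 ± 0.223 to 7.01 CPM (3.94 ± 0.44, adjusted p = 0.000222), S100a6 (2.88 ± 0.36), Ctla4 (2.24 ± 0.34), Maf (1.98 ± 0.32) and Myo6, from 4.10 ± 0.307 to 10.1 CPM (adjusted p = 0.0128). Levels of the effector-memory genes among these were low beside those in effector-memory-like cells of the same library. Scaled by all UMIs of each class, S100a4 stood at 6.94 and 463 CPM there. By the DESeq2 Wald test Ctla4 (0.0701), Maf (0.177), Myo6 (0.514), Sox4 (0.461), Dgkd (0.996) and Chchd10 (0.134) were not called.

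In that comparison 40 of 10101 genes passed, 30 higher and 10 lower. With every library at the naive-like cluster shares of the negative pools, chosen after the data had been seen, 36 passed, 30 of them among the 40, and without cluster 18 of resolution 1.5 it was 33, with 30 among the 40. With those shares Myo6 stood at 1.18 ± 0.28 and lost its call (adjusted p = 0.0821). Without cluster 18 Ctla4 fell to 1.54 ± 0.47 (adjusted p = 0.273), while Sox4 (-0.65 ± 0.14, 0.0538), Maf (1.68 ± 0.37, 0.0526) and Cxcr3 (2.94 ± 0.86, 0.235) lost the call at folds within about 1 SE of those before. Of the key genes Cxcr3 rose (18 UMIs against 6 over the negative pools, 3.68 ± 0.69, adjusted p = 0.0187), and Sell (-0.29 ± 0.09, adjusted p = 0.258), Foxp3 (0.31), Il2ra (1.05), Cd44 (0.33), Pdcd1 (0.39), Gata3 (-0.23), Cxcr5 (2.01), Bcl6 (0.06), Ccr7 (0.03) and Nr4a1 (-0.06) did not pass. Th1/effector genes alone rose as a group (2 of 8, and 3 adjusted over the list alone, 0 lower; camera, adjusted p = 0.000561; adjusted p = 0.585 with an estimated correlation). Fry called 0 of 16 lists there (3 with an unadjusted p under 0.05). Receptor signalling genes had 2 of 15 lower, Cd5 and Cd6, and 0 higher, or 2 and 1 adjusted over the list alone (adjusted p = 0.536). The Cxcr3 and Maf calls were lost when doublets were kept (adjusted p 0.16 and 0.185), that of Cxcr3 also by the DESeq2 Wald test (0.349), and without negative pools 1, 2 and 3 in turn the count of genes was 175, 77 and 79.

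Treg-like cells of the ApoB-positive pool held more Maf and less Ikzf2 than those of the negative pools. They numbered 117, against 152, 293 and 310. Among them 10.8% at equal depth (5.71 to 18.1%, 12 of 111) held at least 2 effector-memory markers, against 2.07%, 3.91% and 2.63% in the negative pools (24.8% against 2.63%, 7.17% and 7.42% with all UMIs; 10.8 to 15.3% over 5 draws), so the clusters may hold some other cells. Maf (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794) stood at 72.3 CPM against 7.18 ± 4.85 (log2 fold 3.14 ± 0.42, adjusted p = 2.32e-10). The other rises were Ahnak (2.09 ± 0.42), the glutaredoxin gene Glrx (1.94 ± 0.33), Matk (1.94 ± 0.45), Cst7 (1.87 ± 0.38) and Ctla4, which encodes a receptor Treg cells use for suppression, from 59.4 ± 11.4 to 149 CPM (1.33 ± 0.23, adjusted p = 7.22e-06). Ikzf2, the Helios transcription factor of thymus-derived Treg cells, was named after its value was seen: it fell from 513 ± 35.2 to 221 CPM (-1.22 ± 0.16, adjusted p = 3.37e-11). Foxp3 stood at 174 against 200 ± 14.7 CPM (-0.22 ± 0.19, adjusted p = 0.819), and Il2ra did not pass either (-0.13).

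Among the 5 largest falls in Treg-like cells, Sox4 had 0 UMIs against 57 over the negative pools, at least 3.46-fold lower. Gsta4 had 3 against 132 (ratio 0.125, 0.0254 to 0.373), Eno3 3 against 97 (0.170, 0.0344 to 0.511) and Dnajc17 1 against 64 (0.0858, 0.00214 to 0.495), while Itm2a fell by 1.98 on the log2 scale. The Eno3 call was lost without negative pool 2 (adjusted p = 0.0913), and the Dnajc17 call without pool 3 (0.101). The low-count rule of DESeq2 left all 11 genes of the naming rule that edgeR called here, Maf and Ctla4 among them, without an adjusted p. In all 51 of 6314 genes passed, 28 higher and 23 lower, or 42 and 20 with total counts only. Of 14 Treg genes 2 rose and 4 fell (2 and 7 adjusted over the list alone; camera, adjusted p = 0.061), and camera called 0 of 14 lists (4 with an unadjusted p under 0.05), as did fry (2 unadjusted). Cd44 (1.42 ± 0.41, adjusted p = 0.056), Gata3 (-0.48), Sell (-0.41), Cxcr3 (2.22), Pdcd1 (-0.40) and Ccr7 (0.01) did not pass, and Nr4a1 had 3 UMIs against 41 (ratio 0.402, 0.0796 to 1.26).

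All other T cells, neither naive-like nor Treg-like, differed most, and here the 2 groups hold different classes. Effector-memory-like cells were 569 of 964 such cells in the ApoB-positive pool and 41 of 554, 75 of 881 and 76 of 908 in the negative pools, where interferon-like cells were the largest class. Lgals3 (log2 fold 5.24 ± 0.36), Ccl5 (5.20 ± 0.15), Cxcr6 (4.65 ± 0.23) and Ifng (4.62 ± 0.35) rose, and Ccr10 had 78 UMIs against 2 (ratio 79.3, 21.2 to 666). Igfbp4 fell from 455 ± 16.1 to 137 CPM (-1.74 ± 0.09, adjusted p = 2.29e-16), beside Tmem108 (-2.25 ± 0.38), Tbc1d16 (-2.19 ± 0.49), Ifi44 (-2.01 ± 0.47) and Irgc1 (-1.84 ± 0.38). Foxp3 rose here, from 9.47 ± 3.68 to 27.3 CPM (1.47 ± 0.23, adjusted p = 1.57e-05), with Il2ra (1.10), Ctla4 (1.54), Gata3 (0.69 ± 0.13), Cd44 (2.21 ± 0.17), Cxcr3 (3.02), Tbx21 (2.20), Rorc (2.93), Ccr6 (2.38), Cxcr5 (2.35) and Pdcd1 (1.02). Sell (-0.90), Ccr7 (-0.59) and Nr4a1 (-0.75 ± 0.16) fell, and Bcl6 did not pass (0.21). The DESeq2 Wald test kept 12 of these 24 calls. It lost Foxp3 (0.0593), Il2ra (0.547), Tbx21 (0.651), Rorc (0.611), Ccr6 (0.167), Pdcd1 (0.106), Gata3 (0.172), Nr4a1 (0.214), Lgals3 (0.132), Tbc1d16 (0.192), Ifi44 (0.204) and Irgc1 (0.136).

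Of 9212 genes tested in these other T cells 909 passed, 524 higher and 385 lower. With total counts only the split was 1091 and 194 and the median of all genes shifted by 0.17 on the log2 scale. Interferon response genes fell (14 of 17 lower, 0 higher, or 15 and 0 adjusted over the list alone; camera, adjusted p = 4.44e-09; adjusted p = 0.325 with an estimated correlation), as did naive genes (11 of 15 on both scales, over all genes and adjusted over the list alone; 6.89e-09, and adjusted p = 0.12 with an estimated correlation). Treg genes rose (9 of 13 higher, 0 lower, or 10 and 1 adjusted over the list alone; adjusted p = 4.39e-05; adjusted p = 0.325 with an estimated correlation). Camera called 12 of 17 lists at the preset correlation, 0 with an estimated one (6 with an unadjusted p under 0.05), and fry called 11. Without negative pool 1 the count of genes was 481, and the calls of Il2ra, Tbx21 and Rorc were lost (adjusted p 0.0558, 0.133 and 0.0853). Without pool 3 those of Tbx21 and Ifi44 were lost (0.0801 and 0.0658).

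Effector-memory-like cells were compared between groups after the data had been seen, with 569 ApoB-positive cells against 41, 75 and 76. The 2 groups hold different mixes of them. At resolution 1.5 most split into the effector-memory-like cluster 14 (18, 20 and 24 negative and 319 ApoB-positive cells) and the Treg-like cluster 15 (21, 54, 52 and 206), so the differences below can come from the mix. Ccl5 stood at 588 CPM against 111 ± 45.8 (log2 fold 2.49 ± 0.22, adjusted p = 8.08e-27), Cxcr6 at 141 against 32.3 ± 10.3 (2.13 ± 0.32, adjusted p = 1.32e-08) and S100a4 at 524 against 270 ± 143 (0.90 ± 0.19, adjusted p = 0.000491). These 3 genes also help to define the clusters. All p-values of this fit use a spread shared over genes, not the SD of the gene itself. Lgals3 (2.82 ± 0.71) and Ly6c2 (1.88 ± 0.48) rose too. Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245) fell from 901 ± 284 to 289 CPM (-1.67 ± 0.18, adjusted p = 2.69e-17). The costimulatory receptor genes Tnfrsf4 (-1.51 ± 0.19) and Tnfrsf9 (-1.77 ± 0.26), the tetraspanin gene Cd81 (-1.93 ± 0.29) and Penk (-2.07 ± 0.55) fell as well. Ctla4 (-1.06 ± 0.24) and Pdcd1 (-1.02 ± 0.24) fell, Foxp3 stood at 57.2 against 108 ± 38.2 CPM (-0.98 ± 0.29, adjusted p = 0.0533), and Cxcr3 (0.20) and Cd44 (0.68) did not pass.

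In these cells 5 of 7 Th1/effector genes rose and 0 fell, the same adjusted over the list alone (camera, adjusted p = 5.9e-09), and 4 of 14 activated/memory genes rose (9 adjusted over the list alone; 4.61e-08). Of 12 Treg genes 6 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 1.58e-12), and of 8 anergy/exhaustion genes 3 fell (6 adjusted over the list alone; 1.88e-06). With an estimated correlation each of these 4 lists had adjusted p = 0.309. Camera called 10 of 14 lists at the preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05, and fry called 0, with 2 unadjusted. In total 40 of 3317 genes passed, 21 higher and 19 lower, or 13 and 26 with total counts only, and the DESeq2 Wald test called 3. It lost Ctla4, Pdcd1, Lgals3, Cxcr6, Ly6c2, S100a4 and Penk, and also Cd81 (0.0762) and Tnfrsf9 (0.270). Without a low-count filter the median of all genes shifted by 0.15 on the log2 scale. Without negative pool 3 the count was 19, and the calls of S100a4, Lgals3, Ly6c2, Ctla4 and Penk were lost (adjusted p 0.302, 0.45, 0.486, 0.71 and 0.238). Those of Pdcd1 and Penk were lost without pool 1 (0.299 and 0.151) or pool 2 (0.123 and 0.996), and that of Lgals3 without pool 1 (0.111), while Ly6c2 stood at -0.00 when doublets were kept.

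Effects were also compared directly between classes, as interaction terms. The ApoB-positive effect differed between Treg-like and naive-like cells for 45 of 9825 genes (7 with a higher and 38 with a lower log2 fold in Treg-like cells). Between other and naive-like cells it differed for 612 genes (232 higher, 380 lower), and between effector-memory-like and naive-like cells for 33 of 10261 (17 higher, 16 lower). For Maf the fold in Treg-like cells exceeded that in naive-like cells by 1.19 ± 0.51 (adjusted p = 0.53), and for Ikzf2 it lay lower by 1.05 (difference -1.05 ± 0.36, adjusted p = 0.243), so neither change was shown to be specific to Treg-like cells. Without negative pool 1 the Treg-like count rose to 72 and edgeR gave an effector-memory-like count of 0 (469 genes at an unadjusted p under 0.05), and that count was 21 without pool 2, 16 without pool 3 and 25 with DESeq2 size factors.

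Shares of cells with a UMI of a key gene were compared at an equal depth of 2200 UMIs per cell. Cxcr3 was found in 5.09% of ApoB-positive cells (4.27 to 6.01%) against 0.267% in the negative pools (range 0.182 to 0.378%), or 7.26% against 0.515% with all UMIs, and in 0.577% of ApoB-positive and 0.0392% of negative naive-like cells. Ctla4 was found in 4.27% (3.52 to 5.12%) against 0.999% ± 0.179 (6.77% against 1.93% with all UMIs; naive-like 1.41% and 0.224%). Foxp3 was found in 3.49% (2.82 to 4.28%) against 2.35% ± 0.449 (5.34% against 3.58% with all UMIs; naive-like 0.577% and 0.360%). Cd44 reached 6.91% against 2.37% ± 0.0530 (11.7% against 3.76% with all UMIs), with 2.63% and 2.25% of naive-like cells, and Pdcd1 2.99% against 0.942% (5.00% against 1.54% with all UMIs; naive-like 0.706% and 0.308%). This naive-like Pdcd1 pair is the widest of the 5 draws. Over the draws it ran from 0.321 to 0.706% in the ApoB-positive pool and from 0.308 to 0.410% in the negative pools. The ratio ran from 0.785 to 2.29, so the direction changed between draws and no naive-like Pdcd1 difference is shown. Sell was found in 28.7% (26.9 to 30.5%) against 37.7% ± 1.90, and in 42.8% against 50.8% with all UMIs. For Gata3 the shares were 8.66% against 8.64% ± 0.281. Il10 and Il17a were found in 0 of 2576 ApoB-positive cells, which allows up to 0.143% of cells with a UMI. Over 5 draws the ApoB-positive shares were 5.09 to 5.59% for Cxcr3, 3.65 to 4.27% for Ctla4, 3.38 to 3.65% for Foxp3, 5.98 to 6.91% for Cd44, 2.68 to 3.07% for Pdcd1, 27.9 to 28.7% for Sell and up to 0.0776% for Il10. Gata3 was found in 8.66 to 10.4%, against 8.34 to 8.64% in the negative pools, so its shares above are the nearest of the 5 draws. Naive-like cells had median depths of 3987 UMIs in the ApoB-positive pool and 3768, 3228 and 3259 in the negative pools, before thinning.

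Regulators of other helper lineages were sought in cells with a Foxp3 UMI. At equal depth 17 of 90 ApoB-positive Foxp3 cells held a UMI of Tbx21, Rorc, Bcl6 or Gata3 (18.9%, 11.4 to 28.5%), against 16.1% ± 2.70 in the negative pools (40 of 256 cells). With all UMIs the shares were 30.3% (22.9 to 38.5%) and 22.7% ± 2.74. Nearly all of this was Gata3, in 16 of 90 cells. Rorc was found in 1 of 90, and Tbx21 and Bcl6 in 0 of 90, which allows up to 4.02%. With all UMIs, in deeper ApoB-positive cells, Rorc was found in 5 of 142 Foxp3 cells (3.52%, 1.15 to 8.03%) against 0 of 423, and Tbx21, Rorc or Bcl6 in 4.23% (1.57 to 8.97%) against 0.187% ± 0.324. Over 5 draws the shares with any of the 4 were 14.9 to 21.3% and 15.6 to 17.6%. In cells without Foxp3 the thinned shares of any of the 4 were 9.86% and 9.08%. For the 4 together the thinned interval holds the mean of the negative pools, so no difference was detectable at this depth.

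Cells with a Foxp3 UMI lay in other classes in the ApoB-positive pool, a comparison made after the data had been seen. Of the 90 ApoB-positive Foxp3 cells 55.6% (44.7 to 66.0%) were effector-memory-like, against 7.15% ± 1.43 in the negative pools, and 30.0% (20.8 to 40.6%) were Treg-like, against 77.5% ± 2.96. With all UMIs the effector-memory-like shares were 47.2% (38.8 to 55.7%, 67 of 142) and 8.89% ± 1.43, and the Treg-like shares 35.2% and 72.5% ± 2.51. Over 5 draws of the thinning the ApoB-positive shares ran from 46.8 to 55.6% and from 30.0 to 37.8%. At the higher clustering resolution of 1.5 a separate Treg-like cluster, 98.2% of its cells effector-memory-like at resolution 1, was led by S100a6, Maf and Ikzf2, and Treg-like cells then made up 11.9% of the ApoB-positive pool against 7.32% ± 1.49.

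**Figure D3:**
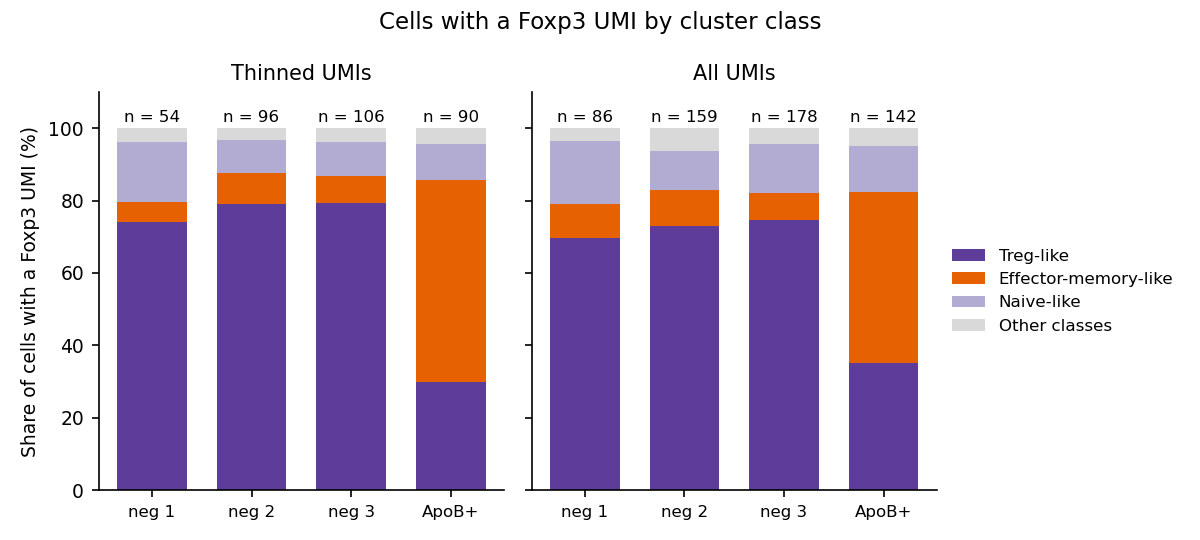
Cells with a Foxp3 UMI by T-cell class, as stacked percent bars for each ApoB-negative pool and the ApoB-positive pool, at 2200 UMIs per cell and with all UMIs. Effector-memory-like cells make up 55.6% of the ApoB-positive bar at equal depth and 7.15% on average in the negative pools.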

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

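The test for memory cells among naive-like cells was written before its result was seen, while the other tests of explanations given here, the exchange of the lone library and the interaction tests within effector-memory-like cells were chosen only after the results had been seen. The separate test of genes that are not fixed markers and the use of both thinned and unthinned Ikzf2 shares were also added after first values were known.

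Effector-memory-like cells made up 21.4% of the ApoB-positive library and 1.63% ± 0.232 of the negative pools (SD, n = 3). A shift of the whole library would have raised the same markers in naive-like cells too. The median log2 fold of 15 fixed markers was 0.51 there and 2.38 over all cells, a ratio of 0.214, and all 15 were smaller in naive-like cells. This cannot decide on a shift, which stays open. Clusters were named by these markers, so cells with raised markers leave the naive-like class. Doublets would hold about the UMIs of a pair of cells, yet the median depth of effector-memory-like cells was 0.872 of that of their library (0.684, 0.794 and 0.757 in the negative pools). Greater depth is argued against by a share of cells with at least 2 markers that was 8.49 times higher at equal depth. Open, as untested, are everything that belongs to the single ApoB-positive preparation, binding of the tetramer without recognition of the peptide, and whether both groups came from the same mice. A difference between cells that bind the tetramer and cells that do not may therefore be kept only as a hypothesis.

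Taking each library in turn as the lone 1 gives 4 splits, too few for a share under 0.05. Where a negative pool is the lone 1, the ApoB-positive library sits in the group set against it and widens that group's spread. Counts of those splits are therefore no yardstick for the real split. The real split called 594 genes over all CD4 T cells, and 1 of the 4 splits, the real one, called as many. The highest of the other splits was 0 by edgeR, with 263, 130 and 268 genes at an unadjusted p under 0.05 for negative pools 1, 2 and 3. Among the negative pools alone, pool 1 differed from the other 2 in 143 genes, pool 3 in 62 and pool 2 in 0 (edgeR, 262 at an unadjusted p under 0.05).

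Treg-like cells of the ApoB-positive pool held less Ikzf2 (log2 fold -1.22) and more Maf (3.14). If only the boundary of the Treg-like cluster had moved, cells with a Foxp3 UMI in any cluster would not differ, and for Maf the tables argue against this, with 28.9% of ApoB-positive Foxp3 cells (19.8 to 39.4%, and 24.5 to 28.9% over 5 draws) against 2.61% ± 2.40. Free Maf RNA from effector-memory-like cells would give naive-like and Treg-like cells a like share, and it is argued against by 1.22% of naive-like cells (0.735 to 1.90%, and 1.22 to 1.54% over 5 draws) beside 14.4% of Treg-like cells (8.47 to 22.4%, and 14.4 to 17.1%). For Ikzf2 a moved boundary and lower expression cannot be told apart. At equal depth 47.8% of Foxp3 cells (37.1 to 58.6%) stood against 45.8% ± 11 in the negative pools. Ratios were 0.8 to 1.04 over 5 draws. With all UMIs 46.5% (38.1 to 55.0%) lay below the negative mean of 55.8% ± 6.54 but within reach of the lowest pool at 50.0%. What belongs to the single preparation, tetramer binding without recognition and the origin of the mice stay open for both genes, and recognition of ApoB may be named only as an untested candidate explanation.

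Of 30 genes higher in ApoB-positive naive-like cells, 4 are fixed effector-memory markers, and the values that free RNA from effector-memory-like cells needs are there: their excess in naive-like cells was 0.834% (Ccl5), 1.05% (S100a6), 1.40% (S100a4) and 1.61% (Cxcr3) of the level in effector-memory-like cells, with a highest over lowest ratio of 1.93 and levels scaled by all UMIs of a class (S100a4 6.94 and 463 CPM), so that free RNA may be their source. Memory cells counted as naive-like would give the same single ratio and cannot be told apart from it for these 4, since the share of naive-like cells with S100a4 that held another marker, 25% (9.77 to 46.7%, 6 of 24, and 10 to 25% over 5 draws), decides nothing where the clusters were drawn on all 17 markers counted, which the test as first written overlooked. Of the other 26 genes, 12 had a lower CPM in effector-memory-like than in naive-like cells, among them Pdlim4, Ly6c1, Myo6 and 6 ribosomal protein genes. For these 12 both sources are argued against as the whole cause. For the rest of the 26 both sources stay open. A different mix of naive-like clusters is argued against as the whole cause, since at resolution 1.5 it gave a median 0.172 of the log2 fold of the 30 genes (quartiles 0.0300 and 0.329), but it gave over 0.5 for Wnt10a (0.663), Capn3 (0.684), Ctla4 (0.540) and Ly6a (0.574), where it stays open. What belongs to the single preparation, tetramer binding without recognition, the origin of the mice and finer mixes of cells were not tested.

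The ApoB-positive effect differed between classes for several named genes, by a test of the difference itself. The log2 fold in Treg-like cells exceeded that in naive-like cells by 1.65 ± 0.35 for Glrx and differed by -3.68 ± 0.93 for Dnajc17, whose 1 UMI in ApoB-positive Treg-like cells leaves the fitted value to the prior count. Both passed without each negative pool in turn.

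Between other T cells and naive-like cells the difference of log2 folds was 4.97 for Lgals3, 3.28 for Cxcr6, 1.87 for Cd44, 1.85 for Ccl5, 0.91 for Gata3, 0.45 for Cd5 and 0.40 for Cd6. It was -2.02 for Tbc1d16, -1.74 for Irgc1, -1.72 for Tmem108, -1.30 for Igfbp4, -0.94 for Sox4, -0.63 for Ccr7 and -0.62 for Sell. By edgeR, Ccl5 missed the threshold without negative pool 1 (adjusted p = 0.153) and pool 3 (0.288), and Cd6 and Tbc1d16 without pool 2 (0.0585 and 0.0604). The class of other T cells holds different clusters in the 2 groups.

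Between effector-memory-like and naive-like cells the difference was -3.38 for Cxcr3, -3.17 for Ctla4, -2.89 for S100a4, -2.26 for Maf, -2.24 for S100a6, -1.53 for Tnfrsf4, -1.47 for Cd81, -1.39 for Ikzf2, 0.68 for Cd5 and 0.80 for Cd6. Without negative pool 1 edgeR called 0 genes (469 at an unadjusted p under 0.05), and these 10 had adjusted p values from 0.144 (Ctla4) to 0.989 (Ikzf2). Without pool 2 the calls of Cd5 (0.177), Cd6 (0.112), Ikzf2 (0.482) and S100a6 (0.0525) were lost, and without pool 3 those of Cd5 (0.221) and Cd6 (0.178). With DESeq2 size factors 25 genes were called in place of 33, and the call of Cd5 was lost (0.125). For Cxcr3, S100a4 and S100a6 the naive-like fold may itself come from free RNA or from memory cells (excess in 1 ratio, 1.93), and the effector-memory-like cells are different mixes in the 2 groups, so these need not be differences in the effect on a class.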

How the results depend on the processing

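The tests of class shares, of effector-memory-like cells alone, of the mix of naive-like clusters and of all cells without the effector-memory-like clusters were chosen only after the data had been seen. The higher effector-memory-like share kept its direction and its side of the threshold at both other resolutions, without the called genes, without doublet removal, with stricter cell filters and without each negative pool, with log2 folds of 1.47 to 4.48 (edgeR, adjusted p 1.34e-09 to 0.0357). Of 2291 further values, for named genes, lists, counts of higher or lower genes and shares of cells, 2001 were the same, 155 lost and 27 gained a call, 38 changed sign and 70 moved (counts by over 1.5 times, shares by more than their spread). No paired analysis was possible because the ApoB-positive group is a single pool whose labels give no replicate number, so the groups share fewer than 2 numbers. With 1 ApoB-positive library each fit of 1 class or of all cells without a negative pool rests on 1 residual degree of freedom, and classes are thin: effector-memory-like cells numbered 41, 75 and 76 in the negative pools, proliferating-like cells 34, 49, 63 and 62 in the 4 libraries, and Treg-like cells 117 in the ApoB-positive pool. Unless said otherwise, the cause of each change given here was not tested.

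With the DESeq2 Wald test, counts of genes were 218 over all CD4 T cells (594 by edgeR, all 218 shared), 11 in naive-like (40), 12 in Treg-like (51), 229 in other (909) and 3 in effector-memory-like cells (40). Of the called genes of the naming rule, it lost 21 of 72 over all cells, 7 of 11 in naive-like, 12 of 24 in other and 9 of 12 in effector-memory-like cells, and its low-count rule gave none of the 11 in Treg-like cells an adjusted p. Without a low-count filter, naive-like cells gave 115. With the class shares of the negative pools the count over all cells was 240, of which 225 were among the 594, and without the effector-memory-like clusters it was 102, of which 97 were. Of the 72 named calls, 18 were lost and 3 untested with those shares, and 33 lost and 13 untested without the clusters, against 7 lost with thinned sums, 4 without doublet removal, 3 with total counts only, 2 with all barcodes and 2 with stricter cell filters. By construction the class shares and the removal of clusters lower the number of effector-memory-like cells in the ApoB-positive sum. The class shares were set for naive-like, Treg-like and other cells alone. They therefore do not bring the effector-memory-like share to that of the negative pools. Camera called 6 lists without those clusters and 0 with an estimated correlation (7 with an unadjusted p under 0.05), against 11. The test with an estimated correlation had little power at 2 residual degrees of freedom.

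With total counts only, Il2ra (0.056), Nr4a1 (0.034) and Cd8b1 (0.013) changed sign over all cells. With the class shares of the negative pools Il2ra (0.20), Gata3 (-0.054), Abcg1 (0.046), Msmo1 (0.025), Cd8b1 (0.090) and Cd68 (-0.28) did. Without the effector-memory-like clusters Foxp3 (-0.26), Bcl6 (-0.29), Gata3 (-0.15), Ccr7 (0.018), Ifi27l2a (-0.026), Scd2 (-0.052), Cd8b1 (0.17) and Cst3 (-0.00015) did, as did the mean log2 folds of the B-cell (-1.32), myeloid (-0.19) and Treg (-0.12) lists. Ccr7 in Treg-like cells stood at -5.69e-05 by DESeq2 and at -0.11 without doublet removal, where Gata3 (-0.0056) and Ly6c2 (-0.0024) changed sign in effector-memory-like cells. In naive-like cells Foxp3 (-0.18) and Nr4a1 (0.0022) changed sign without cluster 18 of resolution 1.5, where 33 genes passed and 4 of 11 named calls were lost (36 and 1 at the cluster shares of the negative pools, with 1 untested). Of all these genes and lists, Ccr7 and Ifi27l2a over all cells and Ly6c2 alone had passed the threshold before, with lists judged by camera. The myeloid list had passed by fry.

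At resolution 1.5, 8 clusters passed in place of 2, the proliferating-like share had a log2 fold of 0.91 and no longer passed, and the Treg-like (0.70) and immediate-early-like (0.24) shares changed sign. For Treg-like cells this goes with a cluster taken from the effector-memory-like cells, which then counts as Treg-like. At resolution 0.6 the Treg-like (-0.56) and interferon-like (-0.33) shares passed, as they did with at least 800 genes and at most 5% mitochondrial UMIs (-0.83 and -0.45). Neither passed among the cells outside the effector-memory-like clusters, where they were -0.23 and -0.0081 at resolution 0.6 (adjusted p 0.867 and 0.926) and -0.49 and -0.12 with those filters (0.284 and 0.855). At the resolution of 1 the naive-like share changed sign outside those clusters (0.015), where the proliferating-like share lost its call (1.21). At resolution 1.5 the naive-like share there stayed lower (-0.38), beside higher Treg-like (0.89) and unnamed (2.92) shares. No cluster took the proliferating-like name at resolution 0.6 or with at least 800 genes, or the immediate-early-like name at 0.6, so these shares have no value there. After clustering without the called genes 1 cluster passed, and the effector-memory-like share without the cells that had that name before was 1.21 times the negative mean, the proliferating-like fold was 0.83 without passing, and the Treg-like (0.25) and immediate-early-like (0.023) shares changed sign. Without doublet removal the proliferating-like fold was 0.63 and did not pass. With all UMIs 1 key gene lay below the negative pools in place of 2. The share of Foxp3 cells with another lineage regulator exceeded the negative mean by 7.56 points with all UMIs and lay at -1.11 points from it with all barcodes, against 2.76.

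Leaving out each negative pool in turn gave 344 (without pool 2) to 1022 (without pool 1) genes over all cells, 77 to 175 in naive-like, 481 to 821 in other and 19 to 41 in effector-memory-like cells. The self-test used all 3 pools, so these fits have no recovery value. Clusters past the threshold ran from 1 (without pool 2) to 3. Log2 folds of shares ran from -0.56 to -0.42 for interferon-like, -0.68 to -0.44 for Treg-like, 0.81 to 1.04 for proliferating-like and -0.33 to -0.28 for naive-like cells. Interferon-like and Treg-like cells passed without pool 1 (not so among cells outside the effector-memory-like clusters, adjusted p = 0.532 for both). Interaction counts ran from 35 to 72 for Treg-like cells and from 0 (edgeR without pool 1, 469 genes unadjusted) to 21 for effector-memory-like cells, where all 3 fits lay below the 33 of the full set.

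Signs changed between these fits for Il2ra (-0.14 to 0.066), Nr4a1 (-0.11 to 0.011) and Cst3 (-0.0036 to 0.047) over all cells, and for the mean of the interferon list (-0.11 to 0.055). In naive-like cells they changed for Bcl6 (-0.019 to 0.12) and Nr4a1 (-0.19 to 0.20), in Treg-like cells for Ccr7 (-0.061 to 0.10), and in effector-memory-like cells for Cxcr3 (-0.21 to 0.47), Gata3 (-0.080 to 0.38) and Ccr7 (-0.084 to 0.27).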

Other observations

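All tests and shares given here were chosen only after the data had been seen. Cells with a Foxp3 UMI carried genes of memory cells more often in the ApoB-positive pool. At 2200 UMIs per cell S100a4 was found in 36.7% of 90 such cells (26.8 to 47.5%) against 2.91% ± 0.928 in the negative pools (SD, n = 3), and the share was 27.6 to 36.7% over 5 draws of the thinning. With all UMIs it was 30.3% of 142 cells (22.9 to 38.5%) against 4.65%, 5.03% and 2.81%. Naive-like cells, as background, held S100a4 in 1.54% (0.989 to 2.28%, and 1.28 to 2.05% over 5 draws) of the ApoB-positive and 0.0628% ± 0.0401 of the negative pools. For Maf, a transcription factor of effector T cells, the share with all UMIs was 33.8% (26.1 to 42.2%) against 4.65%, 5.03% and 7.30%. Of the 27 thinned ApoB-positive Foxp3 cells in Treg-like clusters 0 held S100a4 (upper bound of the interval 12.8%), so all 33 with S100a4 lay in other clusters.

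Ikzf2, the gene of the Helios transcription factor, was found in more cells of the whole ApoB-positive library and in fewer cells of the classes that carry it. Over all cells the thinned share was 6.72% (5.78 to 7.75%) against 4.62% ± 0.934, or 9.97% against 6.45% with all UMIs. Within Treg-like cells it was 25.2% (17.5 to 34.4%) against 52.4% ± 5.20, or 35.0% against 63.9% ± 1.84 with all UMIs. Within effector-memory-like cells it was 23.6% (20.0 to 27.4%) against 44.3% ± 0.695, or 31.5% against 57.1% ± 1.37 with all UMIs. Naive-like cells held it in 0.641% and 0.771% at equal depth. Over 5 draws the ApoB-positive shares ran from 6.60 to 6.99% over all cells, 24.3 to 26.1% in Treg-like and 22.6 to 24.5% in effector-memory-like cells. The effector-memory-like class is a mix that differs between the groups: at resolution 1.5 it splits mostly into the effector-memory-like cluster 14 (18, 20 and 24 negative and 319 ApoB-positive cells) and the Treg-like cluster 15, led by S100a6, Maf and Ikzf2 (21, 54, 52 and 206), and a different mix would lower the Ikzf2 share too.

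Without the effector-memory-like clusters, proliferation genes were also called higher as a group in the ApoB-positive pool, with 8 of 15 higher and 0 lower (camera, adjusted p = 1.95e-12; adjusted p = 0.227 with an estimated correlation). Birc5 stood at a log2 fold of 4.51, Ccnb2 at 4.07 and Pclaf at 3.78. Activated/memory genes had 9 of 13 higher and 0 lower (1.93e-08, and adjusted p = 0.227 with an estimated correlation), with S100a4 at 5.21, S100a6 at 2.68 and Itgb1 at 1.15. Th1/effector genes had 4 of 9 higher (0.000212, and adjusted p = 0.27 with an estimated correlation), with Ifng at 6.17, Cxcr3 at 3.40 and Ccl5 at 2.19. Chemokine receptor genes (3 of 15 higher, adjusted p = 0.000811), follicular helper genes (2 of 10, 0.00201) and anergy/exhaustion genes (1 of 12, 0.0227) passed too, with adjusted p values of 0.27, 0.517 and 0.517 with an estimated correlation. Cd5 was called lower there too (-0.71). Free RNA from the removed cells or memory cells counted as naive-like may be the source of part of this for S100a4, S100a6, Ccl5 and Cxcr3, whose excess in naive-like cells kept 1 ratio to their level in effector-memory-like cells (highest over lowest 1.93).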
